A study of Mus musculus with 12 samples.

How the data were processed

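RNA from the hearts of 12 wild-type C57Bl/6N mice was measured on 12 Affymetrix Mouse Gene 2 arrays, 6 from control mice and 6 from mice given melatonin, per the labels. Mice were 4 weeks old, and their hearts were taken 3 hours into the dark phase and frozen, and biotin-labelled target was made from 500 ng of total RNA, per the labels' protocols. The labels number the samples of each group as biological replicates 1 to 6. The dose, route and duration of melatonin are not given in the sources used here.

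The authors deposited 2 files with the same values for 34351 probe sets, on a log scale that was taken as log2. The largest difference between the 2 files was 0. Every probe set's median over the 12 arrays was 0 to within 5e-07, so the deposited log2 values are the signal of each array minus that median, and they keep no absolute level. The log base, the background correction and the normalization between arrays are not given in the sources used here. A positive value was read as a signal above the median of the 12 arrays, which the files do not state. If the logarithm has another base, every log2 difference and fold below would be rescaled, while the p-values would stay as they are. Array medians lay between -0.0025 and 0.0024, and the median of all values was -2.4e-07.

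Array numbers in the deposited header run with the groups, from 1 to 6 for control and on from there for melatonin. Whether these numbers are the order of processing is not given in the sources used here. If they are, that order and group cannot be told apart, and no batch value could be computed.

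Of the probe sets, 29985 name 1 gene in the deposited annotation, 1888 name several and 2478 name none. The 29469 genes named by a probe set of their own were tested. The values of 384 genes were the mean of several probe sets. Of all probe sets, 5384 carry the annotation's cross-hybridisation type 3, a mark of probes that match other transcripts too, and 558 have no chromosome position. Coordinates are those of the deposited annotation. Of 26084 single-gene probe sets whose symbol is in a GRCm38 gene table, 25907 (99.3%) overlap that table's gene of the same name, so the coordinates are given as GRCm38.

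The design fixed before the data were examined had kept genes above their array's median signal and had used the brightest probe set of a gene. Values centred on each probe set's own median cannot carry either rule, because they hold no level. All genes were therefore tested, with the mean of a gene's probe sets. A comparison of melatonin with control was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), and p-values were adjusted over all genes by the Benjamini-Hochberg method at 0.05. Standard deviations are over 6 hearts, and intervals are 95% intervals of the moderated fit. The number of arrays limits the precision, and without absolute signals the background of a gene cannot be judged.

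Gene lists, fixed before the data were examined, numbered 32: 18 of processes, 13 of cell types and 1 of sex-linked genes. Each was tested with limma's camera at the preset correlation of 0.01, two-sided, and adjusted over the 32 lists. Camera with an estimated correlation and fry were alternatives. Members passing the test were also counted with p-values adjusted over the list alone. The named genes follow a rule fixed at the same time. Where fewer than 10 genes passed in a direction, the rule takes the 10 with the smallest unadjusted p in that direction, leaving out predicted genes, Rik names, microRNAs, olfactory, vomeronasal and sex-linked genes. It adds the 2 members of each list with the smallest unadjusted p, every tested clock gene, and both melatonin receptors. Some genes that the rule takes are not reported here, and they stay in the fits, counts and list tests. Genes outside the rule are named as chosen after their values were seen.

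The fit was tested on simulated data for melatonin against control, with 29469 genes on 12 arrays and the moderated spread of each real gene. It called 40 of 67 genes simulated with a difference of 0.25 log2 (1.19-fold), 67 of 67 at 0.5 log2 (1.41-fold) and 66 of 66 at 1 log2. Of 189 calls, 15 were genes simulated without a difference and 1 was a member of the list shifted in the next test. A simulated shift of 0.1 log2 in the oxidative phosphorylation list was called by camera, with no other list called. Genes were simulated as independent of each other, so this does not show how camera performs where genes vary together. All sizes were simulated in 1 run, and the calls at 0.5 and 1 log2 ease the Benjamini-Hochberg threshold for the rest. Recovery at 0.25 log2 would therefore be lower where few genes differ.

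Alternatives tried were quantile normalization again, subtraction of each array's median, eBayes with trend and robust settings, arrayWeights, limma's treat against a 1.1-fold difference, the replicate number as a block, all probe sets, the other deposited file, and each sample left out in turn. Alternatives chosen after seeing the data were filters on the standard deviation of a gene, on the cross-hybridisation type and on the accession type, and the probe set with the largest standard deviation. For each gene count, list count and Gene Ontology term count, 100 of the 462 possible splits of the 12 hearts into 2 groups of 6 were drawn, the real one included. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.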

Results

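Expression was measured in the myocardium of 4-week-old wild-type mice, 3 hours into the dark phase, to compare 6 control hearts with 6 hearts of mice given melatonin. Melatonin is the hormone that the pineal gland releases at night. Each heart was hybridised to 1 whole-transcript array, and 29469 genes were compared. A gene's values are log2 signals relative to its median over the 12 arrays, with the base of the logarithm taken as 2, so differences between groups are given but no absolute level. Between single arrays, the correlation of these values across genes, which are not independent replicates, ran from -0.21 to 0.14. Centring removes the profile that all hearts share, so these correlations do not measure how well the arrays agree. Across the 12 arrays the standard deviation of a gene had a median of 0.0946 log2.

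No gene differed between melatonin and control hearts at a limma adjusted p under 0.05, and the smallest adjusted p was 0.121. Of the genes taken by the naming rule, Mafk differed by 0.24 log2, Dhx40 by -0.24 and mt-Ts1 by -1.93. An unadjusted p under 0.05 in limma was found for 2748 genes (9.33%), 1289 higher and 1459 lower with melatonin, where 5 percent would give 1473 genes. At an adjusted p under 0.25 the limma fit held 307 genes, 98 higher and 209 lower. The 6 values of each group did not overlap for 212 genes (0.719%), of which 131 were lower and 81 higher, and chance gives 0.216% or 63.8 genes. Group means differed by at least 1.5-fold for 4 genes, the mitochondrial transfer RNA genes mt-Ts1, mt-Ta and mt-Tc and the small cytoplasmic Y RNA gene Rny3, all lower with melatonin. Of these only mt-Ts1 is taken by the naming rule, and the other 3 were chosen after their values were seen. For 99.9% of the genes the 95% interval of the difference lay within 1.5-fold either way, and for 88.8% within 1.2-fold. These shares cover all genes without a filter on level, among them 1443 olfactory and vomeronasal receptor genes taken as silent in heart. They therefore do not bound the change of expressed genes, which centred values cannot set apart. The count of calls moved under 2 settings, the left-out sample and the filter given next. Without control replicate 1, 2 genes passed in limma (Gm17364 at -0.44 log2 and Mir1898 at -0.59, both outside the naming rule and chosen after their values were seen). Among the 14734 genes with the higher standard deviations, fitted on their own, 30 passed, 9 higher and 21 lower. With the p-values of the fit over all genes, adjusted over those 14734, 0 passed in limma (smallest adjusted p = 0.0603).

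Among the genes higher with melatonin that the naming rule takes, none of which passed the adjusted test, Mafk had the smallest unadjusted p. Mafk, a small Maf transcription factor (chromosome 5, 139791513 to 139802653, plus strand, GRCm38), was at 0.15 ± 0.09 log2 (SD, n = 6) with melatonin and -0.09 ± 0.05 (SD, n = 6) in control hearts. The difference was 0.24 log2 (95% interval 0.15 to 0.33; limma adjusted p = 0.121), with all 6 melatonin values above all control values. Clec10a, a lectin receptor of macrophages and dendritic cells (chromosome 11, 70166623 to 70170836), differed by 0.20 log2 (0.12 to 0.27; limma adjusted p = 0.121). Ier3, an immediate early response gene (chromosome 17, 35821684 to 35822923), differed by 0.35 log2 (0.21 to 0.49; limma adjusted p = 0.136). The cartilage matrix gene Matn1 was higher by 0.17, Lingo3 by 0.21, the nucleotide hydrolase gene Dnph1 by 0.24 and the epidermal gene Lce1a2 by 0.23. Tnnc2, the troponin C of fast skeletal muscle, was higher by 0.20. Gbp10, a guanylate-binding protein gene, was higher by 0.34 and the 5S ribosomal RNA gene n-R5s98 by 0.36, both on probe sets marked for cross-hybridisation type 3. Limma adjusted p-values of these 7 genes ran from 0.121 to 0.157. In each of the 10 genes, all 6 melatonin values lay above the control mean.

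The lower genes that the rule takes, which leaves out microRNAs and predicted genes, did not pass either, and Dhx40 had the smallest unadjusted p among them. Dhx40, a DEAH-box helicase gene (chromosome 11, 86768846 to 86807696, minus strand), was at -0.13 ± 0.06 log2 (SD, n = 6) with melatonin and 0.11 ± 0.05 (SD, n = 6) in control hearts. The difference was -0.24 log2 (95% interval -0.31 to -0.16; limma adjusted p = 0.121). Luc7l2, a splicing factor gene, differed by -0.23, Rab14, a small GTPase of endosomal traffic, by -0.27, and Asah1, the lysosomal acid ceramidase gene, by -0.24. Commd6 differed by -0.25, Suco by -0.24 and the lipid transporter gene Abca6 by -0.24. The small nucleolar RNA gene Rnu73b differed by -0.31. The widest difference was that of mt-Ts1, a mitochondrial serine transfer RNA gene (mitochondrial chromosome, 6870 to 6938, minus strand), at -1.93 log2 (95% interval -2.65 to -1.20), or 3.81-fold lower. Its values ran from 0.04 to 1.27 in control hearts and from -2.45 to -0.04 with melatonin. For these 9 genes the limma adjusted p was 0.121, and all 6 melatonin values lay below all control values.

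**Figure D1:**
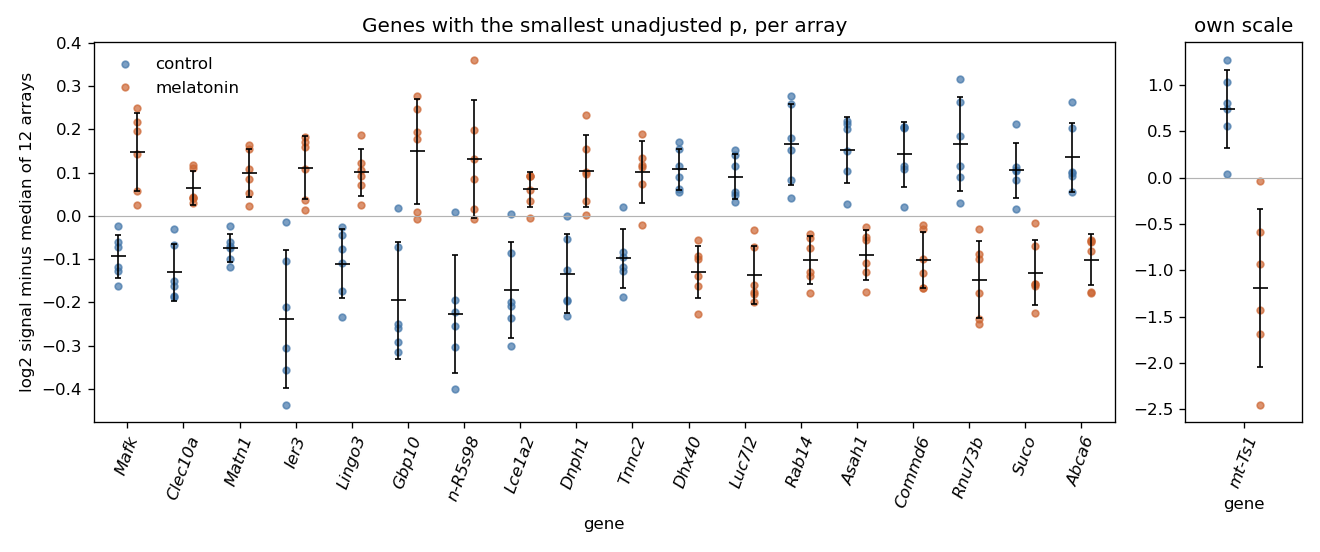
Log2 signal relative to the median of the 12 arrays (vertical axis) for the reported genes chosen by smallest unadjusted p (horizontal axis), with mt-Ts1 on its own scale. Each point is 1 heart, and black bars are the group mean ± SD (n = 6). Mafk lies between 0.02 and 0.25 with melatonin and between -0.16 and -0.02 in control hearts.

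**Figure D2:**
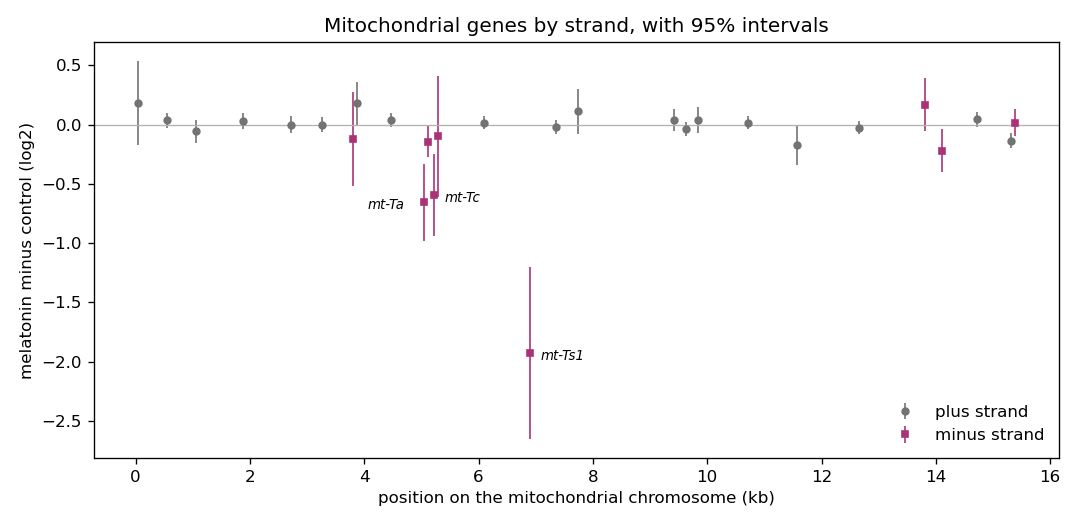
Difference between melatonin and control hearts (vertical axis, log2) for genes of the mitochondrial chromosome by position (horizontal axis, kb), with 95% intervals of the limma fit over 6 hearts per group and strand by colour and symbol. The 3 lowest points are the minus-strand transfer RNA genes mt-Ts1 at -1.93, mt-Ta at -0.66 and mt-Tc at -0.59.

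The list of circadian clock genes bears on hearts collected in the dark phase. Of 17 tested clock genes, 10 were lower and 7 higher with melatonin, and none passed over all genes. Adjusted over the list alone, 3 passed in limma and were lower. These were Nr1d2, a heme-binding repressor of the clock loop, at -0.21 log2 (95% interval -0.33 to -0.09; adjusted p = 0.0343 over the list alone), the orphan receptor gene Rora at -0.16 (-0.26 to -0.05; 0.0457) and the basic helix-loop-helix repressor gene Bhlhe41 at -0.14 (-0.24 to -0.04; 0.0457). Adjusted over all genes, the limma p of Nr1d2 was 0.233, of Rora 0.307 and of Bhlhe41 0.338. The period gene Per3 differed by -0.11 (-0.22 to -0.01) and Per1 by -0.31 (-0.66 to 0.04), the latter with melatonin values below the control mean in 4 of 6 hearts and a difference of -0.20 without control replicate 5. The listed clock genes Per2 and Tef, on probe sets shared with other genes, were not tested. Their sets, chosen after their values were seen, were at 0.04 for Per2 and -0.02 for Tef. The activator genes Arntl and Npas2 differed by 0.02 and 0.00, and Clock by -0.09. Cry1 differed by -0.04, Cry2 by 0.09, Nr1d1 by -0.04, Hlf by 0.04, Nfil3 by 0.04, Bhlhe40 by 0.06, Ciart by -0.00 and Dbp by 0.01, which was -0.01 after quantile normalization again. The list as a whole had a median difference of -0.02 log2 and did not pass (camera adjusted p = 0.203; adjusted p = 0.765 with an estimated correlation).

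**Figure D3:**
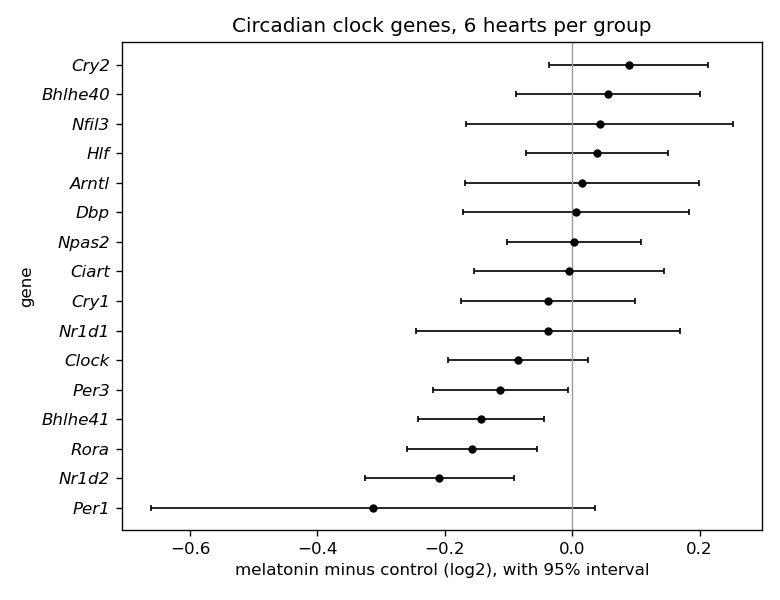
Difference between melatonin and control hearts (horizontal axis, log2) for each reported clock gene (vertical axis), with 95% intervals of the limma fit over 6 hearts per group. The intervals of Nr1d2, Rora, Bhlhe41 and Per3 lie below 0, from -0.33 at the lowest end of Nr1d2 to -0.01 at the upper end of Per3.

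The melatonin receptor genes did not pass the test. Mtnr1a differed by 0.09 log2 (95% interval -0.07 to 0.24; limma adjusted p = 0.787; 0.05 to 0.13 with a sample left out) and Mtnr1b by -0.01 (-0.12 to 0.10; limma adjusted p = 0.981). In the list of melatonin receptors, synthesis and breakdown, 7 of 12 members were higher and 5 lower, with a median of 0.01 (camera adjusted p = 0.765). Gpr50, an orphan receptor related to the melatonin receptors, differed by 0.16, and Nqo2, a quinone reductase that binds melatonin, by 0.14.

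No list passed the camera test after adjustment over the 32 lists, and 3 had an unadjusted p under 0.05, where the other splits of the 12 hearts gave a median of 6. The heat shock and unfolded protein response list had a median of 0.06 log2, with 16 of 22 members higher (camera adjusted p = 0.180; adjusted p = 0.765 with an estimated correlation). Sdf2l1, a chaperone cofactor of the endoplasmic reticulum, was higher by 0.18 and passed adjusted over the list alone (limma adjusted p = 0.0365), and Hsph1 differed by 0.24. Without melatonin replicate 2 the list passed, with a median of 0.07 and a camera adjusted p of 0.0127 (adjusted p = 0.187 with an estimated correlation). The hypertrophy and fetal gene programme list had a median of -0.07, with 10 of 13 members lower (camera adjusted p = 0.203; adjusted p = 0.978 with an estimated correlation). The median was -0.03 without control replicate 4 and -0.04 without control replicate 3. Ankrd1 differed by -0.31 and Xirp2 by -0.18. Fitted on the 14734 genes with the higher standard deviations, the list passed, with a median of -0.10 and a camera adjusted p of 0.0168 (adjusted p = 0.936 with an estimated correlation). Among genes of the list chosen after their values were seen, the natriuretic peptide gene Nppb differed by -0.44 (-1.05 to 0.18) and the skeletal actin gene Acta1 by -0.28 (-0.79 to 0.23), and control replicate 4 held the highest values of both, 1.52 and 1.05.

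The metabolic lists had medians near 0. Fatty acid oxidation had 9 members higher and 16 lower (median -0.02; camera adjusted p = 0.772), with Fabp3 at 0.15 and Ehhadh at -0.10. Glycolysis and glucose use had 10 higher and 13 lower (median -0.01; camera adjusted p = 0.772), with Pfkfb2 at -0.15 and Pdk1 at -0.12. Oxidative phosphorylation had 21 higher and 22 lower (median -0.00; camera adjusted p = 0.941), and its members Ndufa8 and Cox6a2 were at 0.15 and 0.22. For lipid and sterol synthesis, 12 members were higher and 12 lower (median -0.00; camera adjusted p = 0.772). Its member Srebf2, a regulator of sterol synthesis, differed by 0.17. The antioxidant defence list, with Srxn1 at 0.08 and Gclc at -0.10, had 15 higher and 14 lower (median 0.02; camera adjusted p = 0.772). The insulin and growth signalling list had 10 higher and 13 lower (median -0.03; camera adjusted p = 0.320). Its member Igfbp3, an insulin-like growth factor binding protein gene, was lower by a difference of -0.23 and passed adjusted over the list alone (limma adjusted p = 0.00831), and the ubiquitin ligase gene Trim63 differed by -0.16. The glucocorticoid response list had 9 higher and 6 lower (median 0.03; camera adjusted p = 0.941), with Cdkn1a at 0.24 (0.14 to 0.35 with a sample left out).

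The contractile, channel and matrix lists also had medians near 0. The sarcomere and calcium handling list had 9 higher and 13 lower (median -0.00; camera adjusted p = 0.772), with Tnnc1 at -0.09 and Cacna1c at 0.09. Ion channels and gap junctions had 12 higher and 10 lower (median 0.02; camera adjusted p = 0.772), with the potassium channel gene Kcnj2 at 0.19 and Cacnb2 at 0.15. Extracellular matrix genes, with Bgn at 0.19 and Fn1 at -0.12, had 14 higher and 11 lower (median 0.01; camera adjusted p = 0.941). The inflammatory cytokines and adhesion list had 14 higher and 11 lower (median 0.00; camera adjusted p = 0.955), with Ccl2 at -0.13 and Icam1 at 0.09. Interferon response genes, with Ifit1 at 0.21 and Ifih1 at -0.14, had 14 higher and 10 lower (median 0.03; camera adjusted p = 0.941). In the cell cycle list 15 were higher and 13 lower (median 0.01; camera adjusted p = 0.941), with Cdk1 at -0.11 and Tpx2 at 0.10. The immediate early response list had 12 higher and 10 lower (median 0.01; camera adjusted p = 0.772). Its member Ier3 passed adjusted over the list alone (limma adjusted p = 0.00284), and Klf6 differed by -0.10, or -0.04 without melatonin replicate 3.

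Markers of other cell types that a heart sample can hold had medians between -0.02 and 0.05, and none of the 13 lists passed. The white adipocyte list had 9 of 11 members higher (median 0.05; camera adjusted p = 0.320), with Retn at 0.13 and Adipoq at 0.06. The erythroid and blood list had 7 of 9 higher (median 0.05; camera adjusted p = 0.320), with Slc4a1 at 0.19 and Hba-a1 at 0.15. Listed beta-globin genes on shared probe sets were not tested, and these sets, chosen after their values were seen, were at -0.26 (Hbb-bt and Hbb-b2) and 0.03 (Hbb-bs, Hbb-b1 and Hbb-b2). Lymphocyte and thymocyte markers had a median of 0.02 (camera adjusted p = 0.756), and Cd8a, a co-receptor of T cells, was higher by 0.14 and passed adjusted over the list alone (limma adjusted p = 0.044), with Nkg7 at 0.16. Neutrophil markers had a median of 0.02 (camera adjusted p = 0.756), with Ngp at 0.11 and Mmp9 at 0.09. Macrophage markers had a median of 0.00 (camera adjusted p = 0.941), with Lyz2 at -0.16 and Lyve1 at 0.12. For brown adipocyte markers, with Elovl3 at -0.08 and Cidea at -0.07, the median was 0.01 (camera adjusted p = 0.941). For endothelial markers, with Pecam1 at 0.12 and Ushbp1 at 0.10, it was -0.00 (camera adjusted p = 0.955). Smooth muscle and pericyte markers had a median of 0.01 (camera adjusted p = 0.941), with Smtn at 0.12 and Mylk at 0.10. Fibroblast markers, with Lum at -0.15 and Pcolce at 0.09, had a median of -0.01 (camera adjusted p = 0.955). Mesothelial and epicardial markers had a median of 0.02 (camera adjusted p = 0.772), with Upk3b at 0.12 and Wt1 at 0.09. Atrial cardiomyocyte markers had a median of -0.01 (camera adjusted p = 0.772), with Nppa at -0.21. Skeletal muscle markers had a median of -0.02 (camera adjusted p = 0.772), and Tnnc2 passed adjusted over the list alone (limma adjusted p = 0.00369), with Tnni2 at 0.11. Schwann cell and neuron markers had a median of -0.00 (camera adjusted p = 0.941), with Sox10 at 0.16 and Prph at 0.06. The sex-linked list had a median of 0.01 (camera adjusted p = 0.772), with Uty at -0.15 and Ddx3y at -0.10. Over the 32 lists, 9 members of 7 lists passed adjusted over the list alone, a count not corrected for the number of lists. Median and camera direction had opposite signs for 7 lists (lipid and sterol synthesis, brown adipocyte, macrophage, endothelial, skeletal muscle, Schwann cell and neuron, and sex-linked genes), and median and mean for 8, these and oxidative phosphorylation. With fry, and with an estimated correlation in camera, 0 lists passed after adjustment.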

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

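Of the tests weighed here, those of gene and list counts at an adjusted p, of the mitochondrial strands and of the atrial genes were chosen after the result was seen. Among the 94 reported genes, 8 of 188 sets of 6 hearts had 1 heart far from the other 5 by Dixon's ratio of its gap to the range, where 1 in 20 sets, or 9.4, would by chance. In control hearts these were Pdk1 at 0.27 in replicate 6, Cacna1c at 0.24 in replicate 3 and Cdkn1a at 0.55 in replicate 5. With melatonin they were Icam1 at -0.16 in replicate 6, Klf6 at -0.36 in replicate 3, Pecam1 at 0.37 in replicate 2, Smtn at 0.26 in replicate 2 and Nfil3 at -0.32 in replicate 6. These hearts' values are given without an explanation.

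The 2748 genes at an unadjusted limma p under 0.05 were more than any of the other 99 splits of the 12 hearts gave. Of 100 splits only 1, the real one, was as large, and the highest other gave 2500. Only 100 of the 462 possible splits were drawn, so a random grouping is unlikely for this count but not excluded. No gene passed the adjusted test in the real split or in the others (highest other 0), and with a real count of 0 all 100 splits are as large whatever the data, so that comparison decides nothing. A difference in signal range between arrays may add to the count. The median of silent receptor genes (1443 olfactory and vomeronasal genes) minus that of 124 housekeeping genes was 0.0091 log2. In size, 50 of 100 splits matched or passed it, so this measure did not set the real split apart. A range difference as a part of the count was not excluded. The array numbers run with the groups. Whether they are the order of processing is not given in the sources used here, and if so, that order stays open beside melatonin itself.

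The mitochondrial serine transfer RNA gene mt-Ts1 was lower with melatonin by a difference of -1.93 log2. A set of 75 small nucleolar RNA genes had a median of -0.02, so a loss of that size was not shared by this class. Whether other small RNA was recovered less stays open, since 1 class on centred values cannot show it. Less mitochondrial RNA as a whole could not account for that size, since 16 other mitochondrial transfer RNA genes had a median of -0.079. Among them, however, mt-Ta and mt-Tc were at -0.66 and -0.59. A lower level of minus-strand mitochondrial transcripts as a class may contribute: the other 8 minus-strand genes minus 19 plus-strand genes gave a difference of medians of -0.15, which 20 of 100 splits matched or passed, so it stays open. Of 100 splits, 16 gave mt-Ts1 a difference of 1 log2 or more in size, the real one being the widest. A response to melatonin stays open as untested.

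In a comparison also chosen after the result was seen, 29 of 100 splits gave the hypertrophy list a median as large in size. Its median was -0.07 log2, and a random grouping stays open. Another candidate explanation of the list's low camera p is 1 control heart. Without control replicate 4 the median was -0.03 and the p was 0.174, against 0.0163 with all hearts. The p was also above 0.05 without control replicate 3 (0.0685, median -0.04) and without melatonin replicate 6 (0.0583). The atrial genes Sln, Bmp10, Dkk3 and Myl7, with a median of 0.00437, gave no sign of more atrial tissue in control hearts. Of the 11 atrial markers, though, 8 were lower and 3 higher (median -0.01). Nppa, Myl4 and Myl7 are also in the hypertrophy list, so the atrial markers are not fully separate from it. A larger atrial share in control hearts is thus not excluded. A response to melatonin stays open as untested.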

How the results depend on the processing

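The filters and the probe set rule by standard deviation, the cross-hybridisation filter and the accession filter were chosen after seeing the data. The stricter filter on low values and the brightest probe set were not run, because centred values hold no level, and no filter on low values and the mean of probe sets became the reported setting itself. Except where named here, the gene counts, 32 lists and 94 genes kept their direction and their side of the threshold. Genes at an adjusted p under 0.05 in limma stayed at 0 except for 30 in the upper SD filter, refitted on 14734 genes, and for 0 to 2 when a sample was left out (2 without control replicate 1). The refit raised the prior degrees of freedom from 3.38 to 46.1, because genes with a low spread were gone. With the p-values of the fit over all genes and adjustment over the same 14734, added after that count was seen, 0 passed (smallest adjusted p = 0.0603). In the refit Ier3 (0.35), Gbp10 (0.34), n-R5s98 (0.36), Rnu73b (-0.31) and mt-Ts1 (-1.93) passed.

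Genes at an unadjusted p under 0.05 numbered 112 (32 higher, 80 lower) with treat against 1.1-fold, which tests a larger difference, and 1469 (634 higher, 835 lower) in the upper SD filter, with fewer genes tested. With NM accessions only, 748 were higher, again with fewer genes. With a sample left out the count ran from 2376 to 2805. Lists at an adjusted p under 0.05 numbered 1 in the upper SD filter (hypertrophy, median -0.10, camera adjusted p = 0.0168, range over all alternatives 0.0168 to 0.978) and 0 to 1 with a sample left out. The 1 was heat shock without melatonin replicate 2 (adjusted p = 0.0127, range 0.0127 to 0.765). With an estimated correlation, tried after these calls were seen, neither list passed (adjusted p = 0.936 and 0.187). With a sample left out, the median of the hypertrophy list ran from -0.10 to -0.03 and that of the clock list from -0.04 to -0.01. Other lists that kept their sign follow. The erythroid and blood list ran from 0.011 to 0.084 and insulin and growth signalling from -0.042 to -0.0053. The melatonin receptor list ran from 0.0011 to 0.045, fatty acid oxidation from -0.034 to -0.0062 and antioxidant defence from 0.0031 to 0.023. Neutrophil markers ran from 0.0053 to 0.049 and mesothelial markers from 0.00087 to 0.025. White adipocyte markers ran from 0.036 to 0.066 and heat shock from 0.047 to 0.073.

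Of the 32 lists, the medians of 21 changed sign when a sample was left out or under another setting, and none of these passed in any setting. The cause was not tested. After quantile normalization again the medians were -0.0047 for inflammatory cytokines, -2.4e-05 for immediate early, -0.00064 for macrophage and 0.00099 for endothelial genes, and Dbp was -0.0061. With arrayWeights they were -0.0014 for inflammatory, -0.0017 for immediate early, -0.019 for macrophage and -0.00060 for smooth muscle genes, and Dbp was -0.0094. In the upper SD filter they were 0.075 for oxidative phosphorylation, -0.018 for inflammatory, -0.025 for cell cycle, -0.018 for immediate early, 0.023 for endothelial and -0.0018 for smooth muscle genes. With a sample left out, medians ranged as follows: glycolysis and glucose use -0.027 to 0.014, oxidative phosphorylation -0.014 to 0.012, lipid and sterol synthesis -0.014 to 0.022, sarcomere and calcium handling -0.016 to 0.0063, ion channels and gap junctions -0.015 to 0.021, extracellular matrix -0.0082 to 0.038, inflammatory cytokines and adhesion -0.014 to 0.014, interferon response -0.0057 to 0.038, cell cycle -0.0063 to 0.022, glucocorticoid response -0.012 to 0.078, brown adipocyte markers -0.020 to 0.024, macrophage markers -0.041 to 0.036, lymphocyte and thymocyte markers -0.00061 to 0.034, endothelial markers -0.032 to 0.035, smooth muscle and pericyte markers -0.016 to 0.031, fibroblast markers -0.037 to 0.027, atrial cardiomyocyte markers -0.027 to 0.0057, skeletal muscle markers -0.028 to 0.0043, Schwann cell and neuron markers -0.018 to 0.020, sex-linked genes -0.013 to 0.021. Of the 94 reported genes, 21 kept their sign and moved by over 1.5 times with a sample left out. Their ranges were Gclc -0.12 to -0.06, Pdk1 -0.14 to -0.07, Cacna1c 0.07 to 0.15, Bgn 0.12 to 0.25, Fn1 -0.16 to -0.07, Icam1 0.07 to 0.13, Klf6 -0.12 to -0.04, Per1 -0.41 to -0.20, Cdkn1a 0.14 to 0.35, Pecam1 0.06 to 0.14, Mylk 0.05 to 0.12. For the other 10 they were Pcolce 0.06 to 0.11, Wt1 0.04 to 0.13, Nppa -0.33 to -0.11, Prph 0.04 to 0.09, Clock -0.10 to -0.05, Cry1 -0.09 to -0.01, Cry2 0.04 to 0.13, Hlf 0.0018 to 0.07, Bhlhe40 0.0086 to 0.09, Mtnr1a 0.05 to 0.13. The genes that changed sign ranged likewise: Arntl -0.046 to 0.073, Npas2 -0.031 to 0.031, Nr1d1 -0.13 to 0.027, Dbp -0.035 to 0.069, Nfil3 -0.042 to 0.0996, Ciart -0.046 to 0.041, Mtnr1b -0.038 to 0.029.

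Whether the replicate numbers pair the samples stays open. Same-numbered samples deviated from their group means with small correlations of -0.021 to 0.071, but 3 of 6 correlated best with their own number. With the replicate number as a block, 2862 genes had an unadjusted p under 0.05 (1307 higher, 1555 lower) and 0 passed the adjusted test. Signal over background could not be judged from centred values, and 12 arrays limit the precision.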

Other observations

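The tests of Gene Ontology terms and of list counts were chosen after the data were seen. Among 3779 terms with 10 to 200 tested genes, 104 passed camera at the preset correlation, 100 lower with melatonin and 4 higher, and 0 passed with an estimated correlation (smallest adjusted p = 0.388). The 4 terms with the smallest p were helicase activity with 101 of 134 genes lower (median -0.05 log2), ubiquitin-dependent protein catabolism with 101 of 150 (-0.04), the nuclear inclusion body with 12 of 12 (-0.11) and the catalytic spliceosome with 68 of 87 (-0.04). The count of 104 terms was reached by 7 of 100 splits of the hearts, with 309 as the highest other, so a random grouping could not be excluded and may account for it.

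At the preset correlation, 80 of 100 splits called 1 fixed list or more, with 12 lists as the highest other, while the real split called 0. The other splits gave a median of 6 lists at an unadjusted camera p under 0.05, where 5 percent gives 1.6. A low camera p at the preset correlation was thus common without a split by melatonin, and alone it is weak evidence here. Whether a structure among the 12 hearts moves whole gene sets at that setting was not tested. With a real count of 0, all 100 splits give at least as many lists, and 80 gave more. The count of Gene Ontology terms lay the other way, reached by only 7 of 100 splits. Together these counts do not decide whether the split by melatonin follows such a structure.

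Genes outside the rule are given as values, chosen after they were seen. The microRNA gene Mir1898 differed by -0.54 log2 (limma adjusted p = 0.121). Major urinary protein genes, on probe sets marked for cross-hybridisation, were high in control replicate 1 (Mup15 at 2.12, Mup13 at 2.06 and Mup1 at 1.98). Mup15 was at 0.95 in control replicate 5 and 0.90 in melatonin replicate 5, and the liver gene Alb was at 0.88 in melatonin replicate 5. Erdr1 was at -1.44 in melatonin replicate 1 and -1.41 in melatonin replicate 5. A probe set shared by Hspa1a and Hspa1b, outside the tested genes, differed by 0.39 (95% interval 0.03 to 0.76). Hspa1a on its own probe set, tested in the heat shock list, differed by 0.41 (0.08 to 0.74; limma adjusted p = 0.434).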
